A study of Homo sapiens with 12 samples.

How the data were processed

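RNA was measured by sequencing in 12 tumour samples of a high-grade serous ovarian cancer grown in mice as a patient-derived xenograft. The deposited table holds whole-number counts of reads for 26485 human gene symbols in each of the 12 libraries, and per the labels the libraries were made from total RNA with the TruSeq RNA Library Prep Kit v2, a kit that does not mark strand. The submitters' processing notes name TopHat2 2.0.14, Bowtie2 2.2.6, featureCounts 1.4.6 and Subread, and the genome builds hg38 and mm10, without giving the role of each. Whether mouse reads were removed before counting, the annotation and the treatment of reads that match several genes are not given in the sources used here, so a part of the counts of a human gene could come from mouse cells of the host or from a near-identical human gene. No mitochondrially encoded gene is in the table, so the mitochondrial share, a usual sign of RNA quality, could not be computed.

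Total counts per library ranged from 59209277 to 84831623. At this depth 3 counts, the floor used where a gene had none, correspond to 0.0356 to 0.0502 CPM, counts scaled to the total of the library. Floors and counting intervals cover counting error only, since reads amplified by PCR without molecular identifiers are not independent molecules. Within groups, the correlation of log2 CPM across genes lay between 0.9805 and 0.9933, and the lowest chi-square per gene, over genes with at least 20 counts, between a pair of libraries of one group was 15.9, so no pair agreed within sampling noise and all 12 libraries were kept.

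Samples were grouped by their labels, which give the phenotype, the passage and the treatment. Replicate numbers follow the order of the samples, name a library and pair nothing. The series text speaks of 3 experiments that the labels do not assign to samples, so a difference between experiments could not be modelled. The labels do not say for each sample that it came from a separate mouse, so p-values measure the spread between these samples, which may in part be technical. Nor do they say whether the resistant tumours share a lineage, so these may not be independent cases of resistance.

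Counts were tested with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, with robust dispersions, TMM scaling and the default filter on low counts over the 5 groups, which left 17140 genes. All 12 libraries entered one model with 5 group means and 7 residual degrees of freedom, because groups of 2 or 3 are too small to estimate the spread alone. The common biological coefficient of variation was 0.174. Adjusted p-values follow Benjamini and Hochberg over all genes tested within a comparison, with a threshold of 0.05, and a gene is said to rise, fall or change only where it passed. The standard error (SE) of a log2 fold change was taken from the F statistic. In comparisons with the resistant tumours, the means of the passage 2 and passage 3 groups were averaged. Levels are CPM scaled with the TMM factors, given as mean ± SD.

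Gene lists were written from textbook knowledge before the data were examined. Of 34 lists, 33 had a tested member, and each was tested with camera of limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation between genes of 0.01, adjusted over the lists of a comparison. The same lists were run with the correlation estimated from the data and with fry, which asks whether the members move on balance in one direction. The rule for the genes to be named was fixed at the same time. They are the 10 with the largest rise and the 10 with the largest fall for the comparisons of resistant with source, treated sensitive with source and resistant with treated sensitive tumours, and 3 and 3 for the others. These had to pass the threshold, have a mean log2 CPM of at least 1 and not overlap between the libraries compared. Uncharacterised loci, non-coding RNAs, X-inactivation transcripts and Y-linked genes were passed over. Up to 4 members per list with the smallest adjusted p, and PARP1, PARP2 and ABCB1 always, were added. Some genes that this rule selects are not reported here. Other genes named in the text are said to have been chosen after their values were seen.

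Alternatives were RLE scaling, no filter on low counts, DESeq2 1.42.0, a model of only the libraries compared, the resistant tumours as 1 group, each resistant passage alone, and each library left out in turn. Gene positions were read from GENCODE release 29 on GRCh38, the assembly of hg38, by gene symbol, and 92.9% of tested genes had one.

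The test was tried on simulated counts with the real means, library sizes and dispersions, with 200 changed genes per comparison. For resistant against source tumours, 16882 genes were run, 83% of 2-fold changes and 100% of 4-fold changes were recovered, and 11 unchanged genes were called. For treated sensitive against source tumours, also 16882 genes, the recovered shares were 73% and 96%. For resistant tumours of passage 3 against passage 2, 16881 genes, they were 78% and 95%. The changed genes were drawn from those above a minimum level, and the simulated genes varied independently. These shares therefore do not hold for weakly expressed genes or for genes that vary together.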

Results

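Gene expression was measured in tumours of a patient-derived xenograft, human high-grade serous ovarian cancer kept by passage in mice, before and after treatment with niraparib. Niraparib inhibits PARP1 and PARP2, enzymes that signal DNA breaks, and is used against tumours that repair such breaks poorly. Treated tumours received 100 mg/kg in cycles of 21 days, with 4 rounds in the whole study. The libraries comprised 3 source tumours of passage 3 that were sensitive, 2 treated tumours of passage 1 that were still sensitive, 2 treated tumours of passage 1 with a mixed phenotype, 2 resistant treated tumours of passage 2 and 3 resistant treated tumours of passage 3. These numbers follow the sample labels. The series text gives other group sizes, of 3 treated or 2 source tumours, and 3 experiments, which are not assigned to samples. Total counts per library lay between 59209277 and 76014479 in the source tumours, 64234213 and 77267716 in the treated sensitive and 71187348 and 74535260 in the mixed tumours. They lay between 61140036 and 65268406 in the resistant tumours of passage 2 and between 69082150 and 84831623 in those of passage 3. The 28S ribosomal RNA took 1.12% of the counts in source replicate 3, where it was the largest gene.

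The libraries separated by phenotype. The first principal component of log2 CPM held 39.3% of the variance. On it the 5 sensitive libraries lay between -51.3 and -26.4 and the 5 resistant libraries between 34.4 and 43.5. The mixed libraries lay at -2.75 and 22.9.

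**Figure D1:**
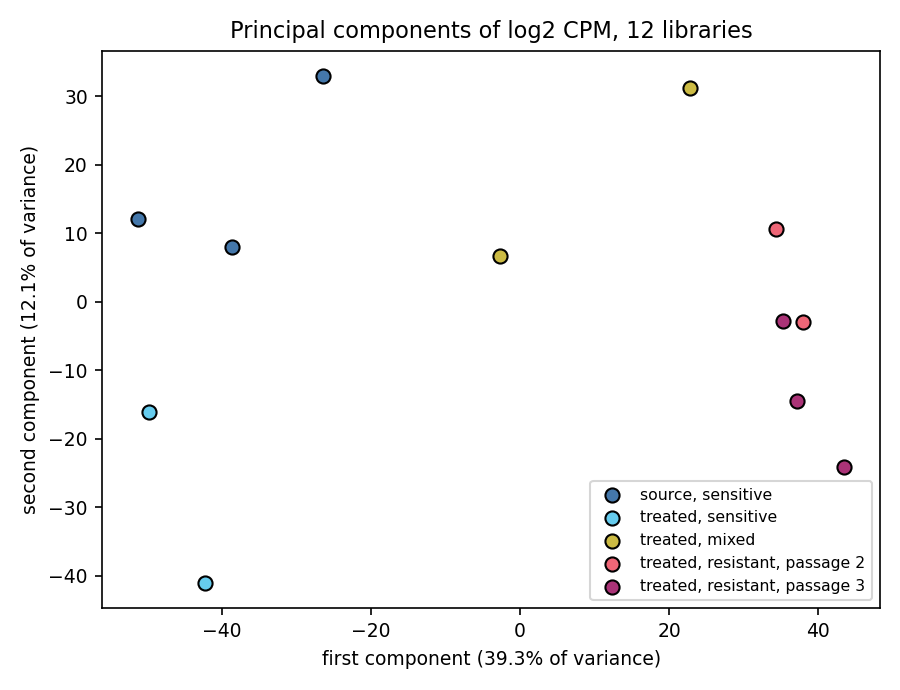
Scores of the 12 libraries on the first (39.3% of variance) and second (12.1%) principal components of log2 CPM, 1 point per library, coloured by group. The 5 resistant libraries lie at the right (34.4 to 43.5), the 5 sensitive libraries at the left (-51.3 to -26.4) and the mixed libraries between them.

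The comparison of resistant with source tumours asks what differs once the tumour no longer responds, and holds treatment and phenotype together. RAD51C, needed for repair of DNA breaks by homologous recombination, had the largest rise among the genes that the naming rule admits. It had 0, 10 and 0 counts in the source tumours and 1099 to 1724 counts in the 5 resistant tumours, or 0.0553 ± 0.0959 CPM (SD, n = 3) against 19.6 ± 1.36 CPM (SD, n = 5). The ratio of the pooled counts was 398, with a 95% counting interval from 216 to 829.9 (edgeR adjusted p = 5.79e-05). RAD51C lies on chromosome 17 from 58692573 to 58735611 in hg38, on the plus strand. TEX14, chosen after its values were seen, begins 518 bases away on the minus strand (58556678 to 58692055) and was also higher, by a log2 fold change of 1.75 ± 0.38 (SE, adjusted p = 0.0081), at 5 to 51 counts per library. With strand unmarked, reads of the 2 genes near their starts could be told apart only by position. The other 23 tested genes within 1 Mb had log2 fold changes between -0.41 and 0.48, and CUEDC1, named for the same reason, was the 1 among them that passed the test (0.44 ± 0.12 SE, adjusted p = 0.022).

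**Figure D2:**
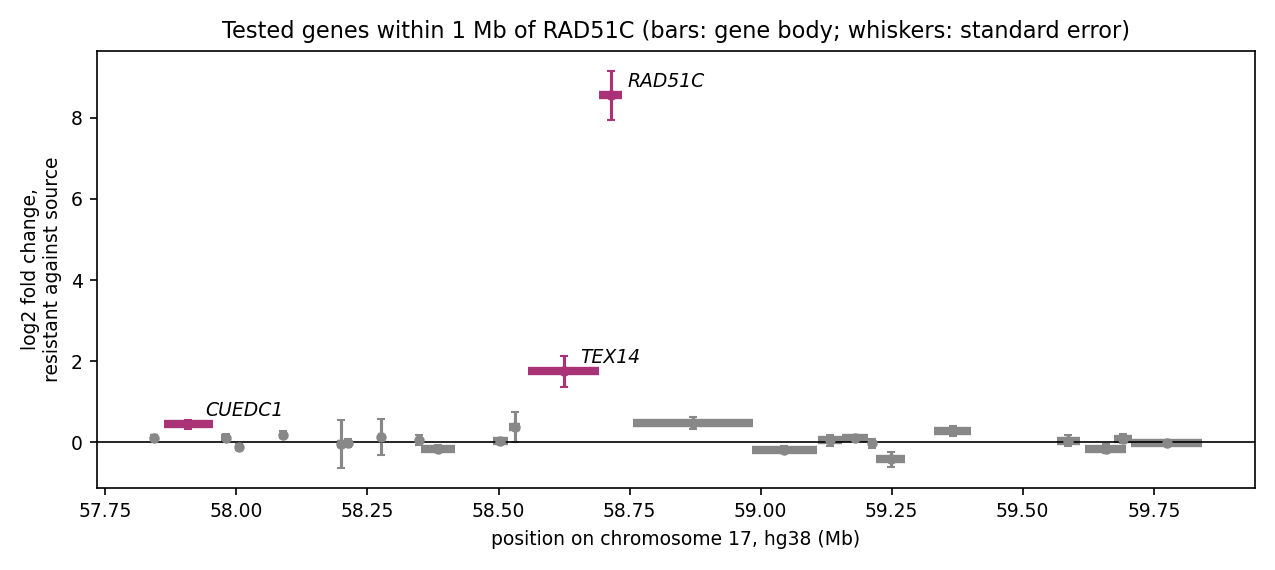
Log2 fold change of resistant against source tumours (vertical axis) for the tested genes within 1 Mb of RAD51C, by position on chromosome 17 in hg38 in Mb (horizontal axis). Bars span the gene body, whiskers are standard errors, and genes that passed the test are named and coloured. RAD51C stands at 8.56, a fitted value that depends on the prior count, and TEX14 at 1.75.

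In all, 2600 of 17140 genes differed between resistant and source tumours, 1329 higher and 1271 lower, of which 390 and 485 changed at least 2-fold. Beside RAD51C, the largest rises were mostly of genes induced by interferon. ZBP1, a sensor of left-handed nucleic acids, rose by a log2 fold change of 5.02 ± 0.90 (SE, adjusted p = 0.0050), and RTP4, OAS2, EPSTI1 and MX2 rose by 4.32, 3.82, 3.71 and 3.55. HLA-F, IFI27, CXCL11 and the zinc finger gene ZMAT4 completed the set with 4.01, 3.61, 3.59 and 3.53. The calls of IFI27 and CXCL11 were each lost in 7 of the 8 runs that left out a library, and that of HLA-F without source replicate 1 or 3. HLA-F shares sequence with other class I genes, so its count is uncertain. The largest falls were of ZNF71, a zinc finger gene with 2 counts in all 5 resistant tumours against 223 to 346 in each source tumour (ratio 689.6, interval 191 to 5694), and of RAB18, a small GTPase, from 35.3 ± 4.92 CPM (SD, n = 3) to 0.186 ± 0.181 CPM (SD, n = 5). MEOX2, a homeobox gene, ANOS1, the inflammasome gene NLRC4, CALML3, AGMO, SH3BGRL and FOXJ1, the regulator of ciliated cells, fell by 5.67, 4.82, 4.62, 4.61, 4.40, 4.28 and 3.99 on the log2 scale. SH3BGRL lost its call without source replicate 1, source replicate 2 or passage 2 replicate 1. RAB18 and CALML3 lie in the first 40 Mb of chromosome 10, where 70.9% of tested genes from 0 to 20 Mb and 61.3% from 20 to 40 Mb fell, windows chosen after the values were seen. Without source replicate 1 the count of changed genes was 1355, without source replicate 2 it was 1610, and with passage 2 alone as the resistant group it was 1375.

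Interferon response genes rose together in the resistant tumours. Of 21 tested members, 19 rose and none fell (20 and 0 adjusted over the list alone), with a median log2 fold change of 2.31. IFI44L rose by 2.31 ± 0.25, IFIH1, which senses double-stranded RNA, by 1.89 ± 0.23, and OAS3 by 1.89 ± 0.23 (SE, adjusted p from 0.00025 to 0.00052). IFIH1 lies on chromosome 2 in a window from 160 to 180 Mb where 37.8% of genes rose. IFIH1 went from 24.6 ± 5.86 CPM (SD, n = 3) to 92.9 ± 23.3 CPM (SD, n = 5). The camera test of the list gave an adjusted p of 9.17e-18, and the adjusted p was 0.61 with an estimated correlation. Of the 14 genes of class I antigen presentation, 12 rose and none fell (14 and 0 adjusted over the list alone). Among them were NLRC5, the transactivator of class I genes, by 2.07 ± 0.28, the peptide transporter TAP1 by 1.46 ± 0.19, and the immunoproteasome subunits PSMB9 by 2.61 ± 0.40 and PSMB8 by 1.36 ± 0.24 (SE). The list gave an adjusted p of 7.99e-10, and 0.61 as the adjusted p with an estimated correlation. PSMB9 overlaps both TAP1 and PSMB8 in the annotation, and PARP9 overlaps DTX3L, so their counts are not separate without strand. Of human immune cell markers, PTPRC, the pan-leukocyte antigen, had 0 to 8 counts in a library, and the macrophage marker CD68 averaged 14.3 CPM in the resistant and 10.5 CPM in the sensitive libraries. Of the ADP-ribosylation genes, PARP9, PARP12, PARP14 and PARP10, themselves induced by interferon, rose by 1.71, 1.42, 1.28 and 1.02, and the list as a whole had an adjusted p of 0.23.

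Cholesterol and fatty acid synthesis moved the other way. Of 22 members, 13 fell and none rose (18 and 0 adjusted over the list alone), with a median log2 fold change of -0.46. The 13 became 5 without source replicate 1, 5 without source replicate 2 and 6 without passage 2 replicate 2, and they were 3 with passage 2 alone and 15 with passage 3 alone as the resistant group. SQLE fell by 0.85 ± 0.13, HMGCS1 fell by 0.44 ± 0.08 and IDI1 fell by 1.32 ± 0.17 (SE, adjusted p from 0.00056 to 0.0038). IDI1 lies in the window of chromosome 10 from 0 to 20 Mb named above, whose genes had a median of -0.67. The list gave a camera adjusted p of 2.42e-08, and 0.61 as the adjusted p with an estimated correlation. NF-kappaB targets were called higher (adjusted p = 0.0074, and 0.80 with an estimated correlation), with 3 of 19 members risen, RELB, IL1B and CXCL5 (1 with passage 2 alone and 4 with passage 3 alone). CXCL5 had at most 117 counts in a library and lost its call without source replicate 1, source replicate 2 or passage 2 replicate 1, and IL1B without source replicate 1. Of 7 tested pancreas, liver and gut markers, PRSS1, SERPINA1 and APOA1 rose and CEL fell (camera adjusted p = 0.039, and 0.61 with an estimated correlation). PRSS1 reached 5.60 ± 1.73 CPM (SD, n = 5) and has close paralogs, so its count is uncertain. CEL lost its call in 6 of the 8 runs that left out a library. Among markers of other cell types, FBN1 was the 1 of 9 fibroblast genes that fell (not without source replicate 1), TEK the 1 of 8 endothelial genes that rose, and UPK1B and PDPN the 2 of 8 mesothelial genes that fell. None of the 6 myeloid and 6 lymphocyte genes tested was called, and none of these lists was (camera adjusted p from 0.256 to 0.699).

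**Figure D3:**
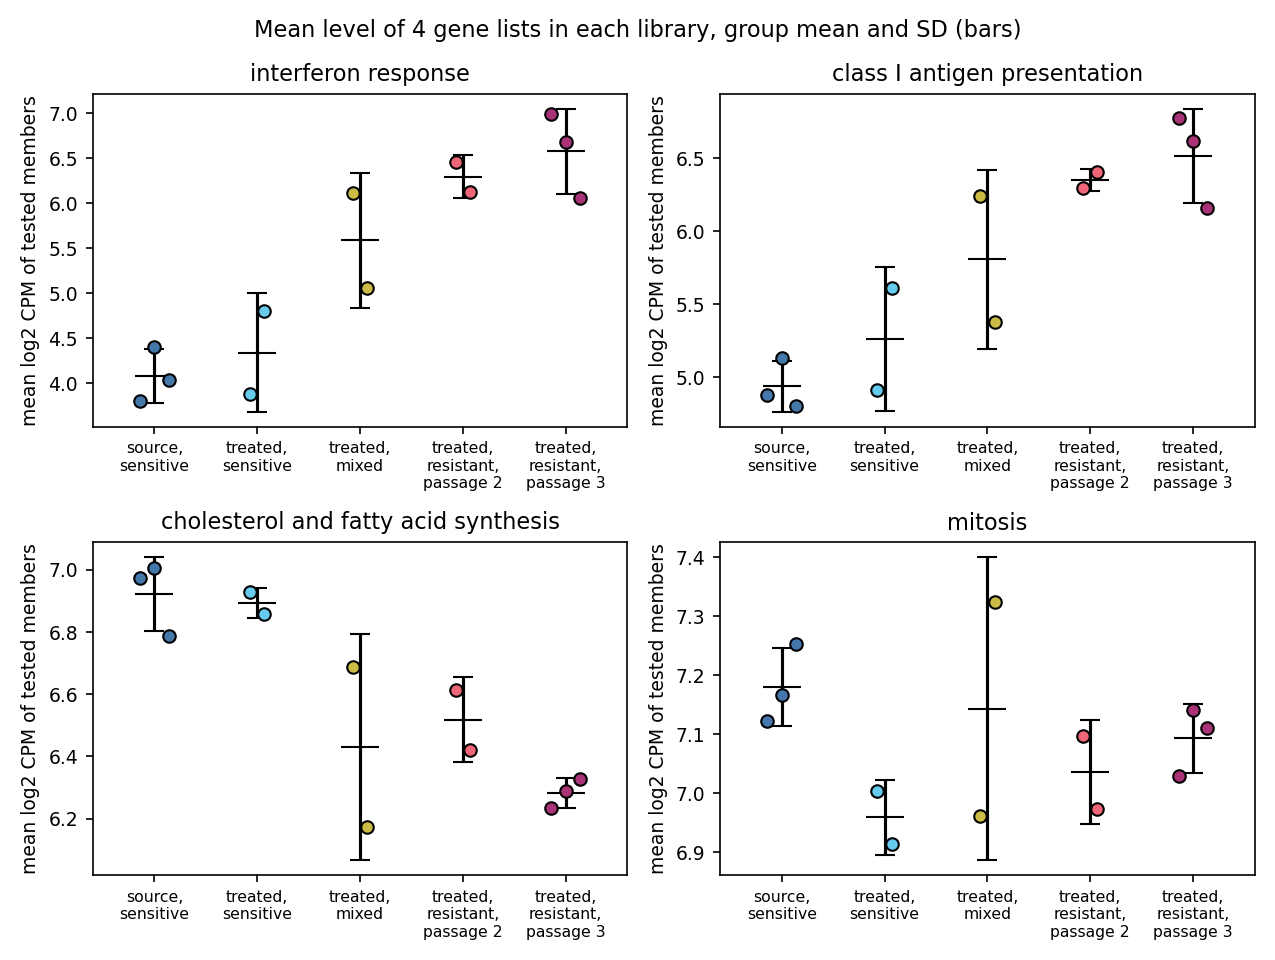
Mean log2 CPM over the tested members of 4 gene lists (vertical axes, which do not start at 0) in each library (points), with group mean and SD (bars), for the 5 groups on the horizontal axes. The lowest resistant library lies above the highest sensitive library for interferon response (6.06 against 4.80) and class I antigen presentation (6.16 against 5.61).

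Of 90 genes in the 5 lists of DNA repair and fork protection, 8 passed the test against the source tumours (8.89%, against 15.2% of all genes). RAD51C was the only one of 22 homologous recombination genes to pass the test, and the list had a median log2 fold change of 0.03 (camera adjusted p = 0.34). Of 15 Fanconi anaemia genes only SLX4 fell, by 0.49, a call lost without source replicate 1 or 2. Of 12 genes of DNA end protection, MAD2L2 and PAXIP1 rose by 0.56 and 0.31. The call of MAD2L2 was lost without source replicate 1 and that of PAXIP1 in 7 of the 8 runs that left out a library, and they lie in windows from 0 to 20 Mb of chromosome 1 and from 140 to 160 Mb of chromosome 7 where 42.5% and 39.1% of genes rose. Of 22 genes of end joining and excision repair, LIG4 rose by 0.53 and DCLRE1C fell by 0.43, and of 19 of fork protection MUS81 rose by 0.35 and SMARCAL1, a fork remodelling enzyme, by 0.47 ± 0.08 (SE, adjusted p = 0.0023). LIG4, DCLRE1C and MUS81 (adjusted p from 0.039 to 0.042) each lost their call in 7 of the 8 runs that left out a library. DCLRE1C overlaps SUV39H2, and MUS81 overlaps CFL1 and EFEMP2. DCLRE1C lies on chromosome 10 from 0 to 20 Mb and SMARCAL1 on chromosome 2 from 200 to 220 Mb, where 70.9% of genes fell and 36.1% rose. No list of DNA repair or replication was called. Of 22 mitosis genes none was called (list adjusted p = 0.203). The drug targets PARP1 (512 ± 52.5 CPM in the source, SD, n = 3, against 501 ± 15.6 CPM, SD, n = 5) and PARP2 (66.1 ± 2.50 against 60.1 ± 1.54 CPM, SD) did not pass the test, with log2 fold changes of -0.03 ± 0.10 and -0.14 ± 0.07 (SE, adjusted p = 0.86 and 0.21). The drug efflux pump ABCB1 had 0 to 6 counts per library and was not tested. Single genes of other lists moved both ways. CCND1, a cell cycle regulator of the MAPK output list, fell by 3.31 ± 0.46 (SE). VIM of the mesenchymal list, also on chromosome 10 from 0 to 20 Mb, fell by 1.57 ± 0.20. Of the serous ovarian identity list, MUC16, which encodes the CA125 antigen, fell by 1.69 ± 0.34, while WFDC2, which encodes HE4, rose by 1.10 ± 0.19. Camera did not call these 3 lists. The keratins KRT8, KRT19, KRT7 and KRT18 fell by 0.53, 0.54, 0.42 and 0.46, and the epithelial list had an adjusted p of 0.0645. KRT19, KRT7 and KRT18 lost their calls without source replicate 1, KRT18 also without source replicate 2, and KRT8 and KRT18 overlap, as do CCND1 and LTO1.

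**Figure D4:**
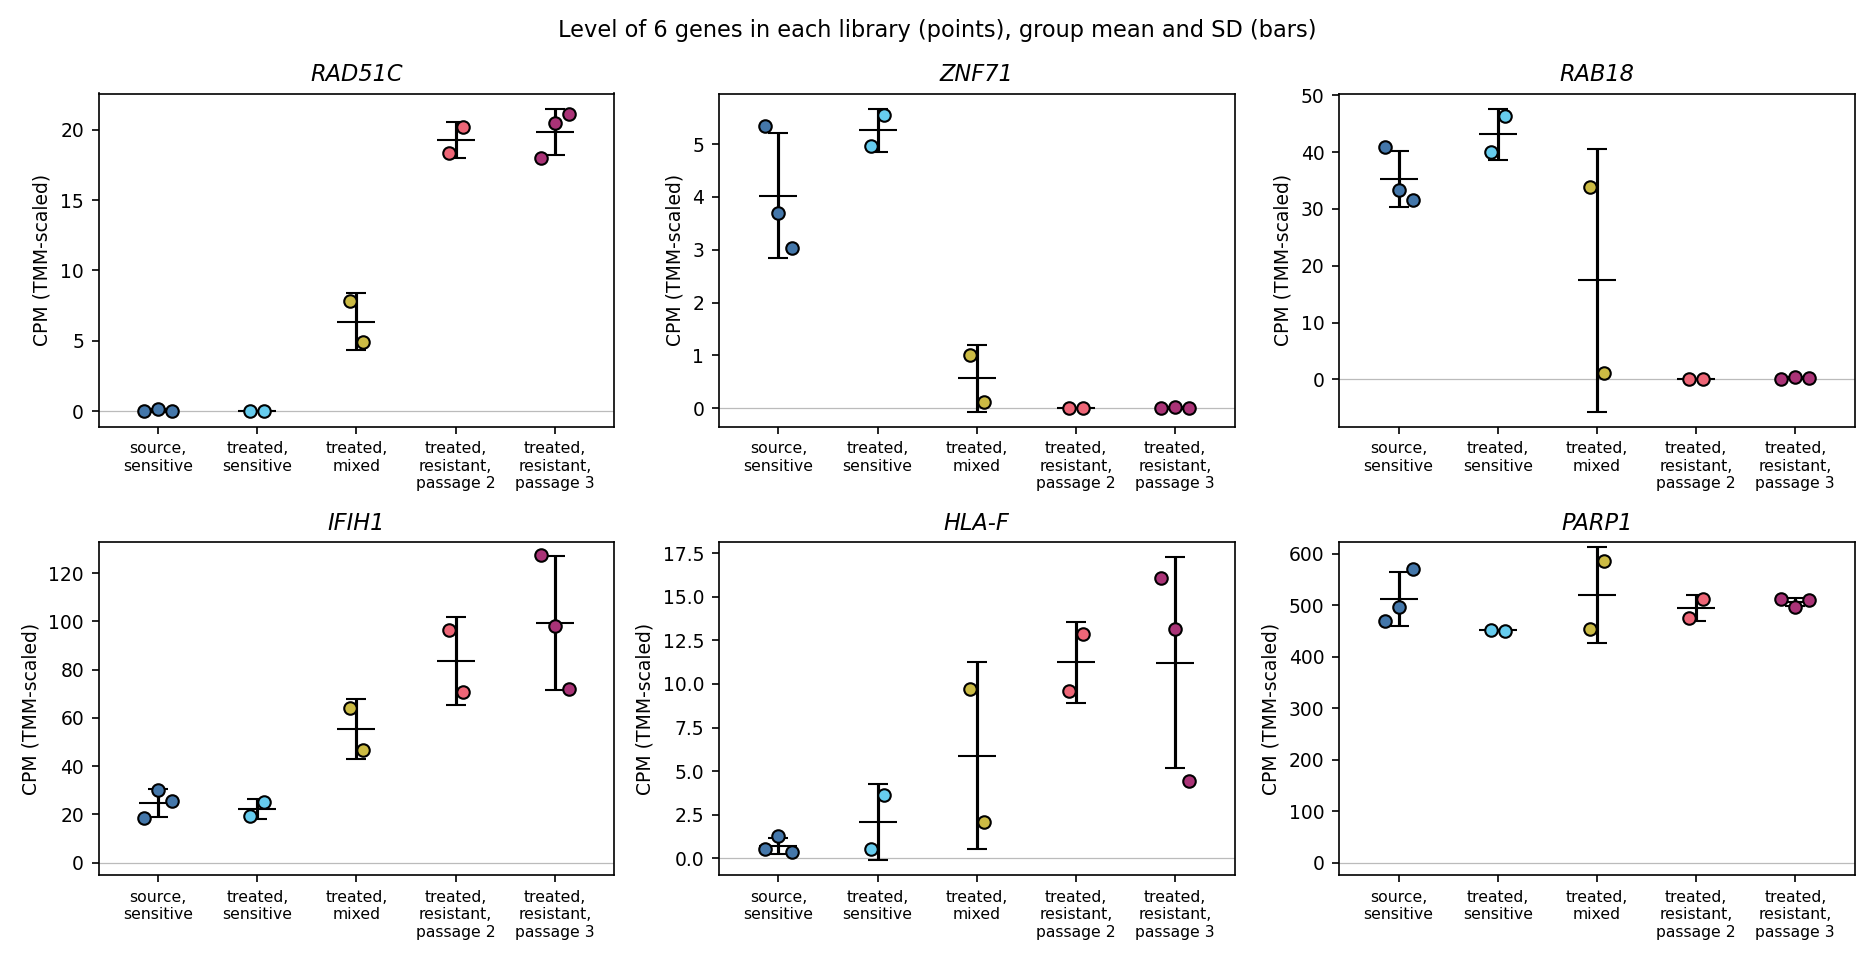
CPM, scaled with the TMM factors (vertical axes), of 6 genes in each library (points), with group mean and SD (bars, which can reach below 0), for the 5 groups on the horizontal axes. RAD51C lies at 0 to 10 counts in the 5 sensitive libraries and averages 19.6 CPM in the 5 resistant ones, ZNF71 and RAB18 are near 0 in the resistant libraries, and PARP1 averages 512 CPM in source and 501 CPM in resistant tumours.

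In the comparison of resistant with treated sensitive tumours both groups were treated, but the passages differ and the rounds each tumour received are not given per sample. RAD51C had 0 counts in both treated sensitive tumours and was at least 928.7-fold higher in the resistant ones against a floor of 3 counts over the group (755-fold at the lower 95% counting limit, adjusted p = 0.00012). ZNF71, RAB18, CALML3, MEOX2, NLRC4, ANOS1, SH3BGRL and AGMO were again among the 10 largest falls, as was IGFBP7 (-4.49 ± 0.70 SE), which overlaps POLR2B. The largest rises beside RAD51C were OAS2, ZNF519, the fibrocystin gene PKHD1, ZMAT4, MX2, EPSTI1, TRIM22, XAF1 and SAMD9L, by 3.19, 3.15, 3.13, 3.07, 3.03, 2.98, 2.92, 2.83 and 2.81. OAS2, ZMAT4, MX2, TRIM22 and SH3BGRL lost their calls without treated sensitive replicate 1, ZMAT4 and SH3BGRL also without replicate 2, and OAS2 also without passage 2 replicate 1. In all 3305 genes differed, 1607 higher and 1698 lower. Leaving out treated sensitive replicate 1 gave 1515 and replicate 2 gave 1274, and passage 2 alone gave 1895.

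Interferon response, class I antigen presentation and cholesterol synthesis were called again, in the same directions, and homologous recombination was called higher. With an estimated correlation none of the 4 was, with adjusted p-values of 0.70 for interferon, class I and homologous recombination and 0.71 for cholesterol. Of 21 interferon genes 18 rose (19 adjusted over the list alone; camera adjusted p = 7.32e-13), although 10 and 13 did so without treated sensitive replicate 1 and replicate 2. Of 14 class I genes 8 rose (11 adjusted over the list alone; adjusted p = 7.15e-06), 3 without treated sensitive replicate 1 and 5 without passage 2 replicate 2, and 11 of 22 cholesterol and fatty acid genes fell (15 adjusted over the list alone; adjusted p = 0.00011), 2 without treated sensitive replicate 1, 3 without replicate 2 and 6 without passage 2 replicate 2. With passage 2 alone as the resistant group, 4 class I genes rose and 1 cholesterol gene fell, and with passage 3 alone 8 and 14 did. Of 22 homologous recombination genes 6 rose and 1 fell (10 and 1 adjusted over the list alone; adjusted p = 0.00053, and 0.70 with an estimated correlation). The risen genes became 1 without treated sensitive replicate 2 and 3 without passage 3 replicate 1, and the fallen gene lost its call whichever of the 7 libraries was left out. XRCC2 rose by 0.78 ± 0.15 and BARD1, the partner of BRCA1, rose by 0.78 ± 0.17 (SE), and both lost their calls without treated sensitive replicate 2. XRCC2 lies on chromosome 7 from 140 to 160 Mb and BARD1 on chromosome 2 from 200 to 220 Mb, in windows where 39.1% and 36.1% of genes rose against source tumours. Of 18 p53 targets 5 fell, among them FDXR by 0.86, TP53I3 by 0.85, BAX by 0.43 and DDB2 by 0.62 on the log2 scale, and each of these 4 lost its call without the one and without the other treated sensitive library. TP53I3 overlaps FAM228B. The list was not called (adjusted p = 0.107, 6 fallen adjusted over the list alone). It averaged 4.58 log2 CPM in resistant, 4.64 in source and 4.72 over all sensitive libraries. The treated sensitive tumours thus lay above the source tumours here. Among markers of other cell types, COL1A2 of the fibroblast list rose by 2.07, TEK of the endothelial by 2.09, PAX5 of the lymphocyte and LRRN4 of the mesothelial list by 1.57 and 0.97, and the mesothelial UPK1B fell by 0.95. PDPN, also mesothelial, fell from 40 counts in the treated sensitive libraries to 0 in the resistant ones, at least 32.7-fold lower against a floor of 3 counts over the group (26.6-fold at the lower 95% counting limit). None of these 4 lists was called (adjusted p from 0.496 to 0.849). TEK had at most 126, PAX5 39 and PDPN 32 counts in a library. COL1A2 lost its call without treated sensitive replicate 1, PAX5 without the one and without the other, and LRRN4, UPK1B and PDPN without replicate 2. The 847 genes higher and 855 lower in both comparisons stand against 124.6 and 125.9 for independent lists and 0 in 20 simulations without any effect. The simulations leave out the real effects and the independent lists leave out the shared resistant libraries, so the excess over either does not measure a shared effect. With no library in common between the groups compared, 462 higher and 492 lower genes were shared. These comparisons were passage 2 resistant against source and passage 3 resistant against treated sensitive tumours. Independent lists would share 55.6 and 54.95. Both tests came from the same model of 12 libraries and share its estimates of spread, so this excess does not measure a shared effect either.

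Mixed and sensitive tumours of passage 1 carry the same passage and drug in their labels and differ in phenotype. The rounds each tumour received are not given per sample. The sample code of mixed replicate 2 has another form than those of the other 3 libraries, the form of the codes of the resistant libraries, so equal treatment is not shown. RAD51C had 554 and 366 counts in the mixed tumours, 7.80 and 4.93 CPM, and 0 in the treated sensitive ones, at least 298.6-fold higher against the same floor (243-fold at the lower 95% counting limit, adjusted p = 0.0038). EPHA3 and NTRK2, a pair of receptor tyrosine kinases, rose by 4.30 ± 1.04 and 2.47 ± 0.65 (SE), and NMUR2, OBP2A and the homeobox gene BARX1 fell by 3.90, 3.83 and 3.52. OBP2A has a near-identical copy, so its count is uncertain. The calls of EPHA3, NTRK2 and NMUR2 were lost without mixed replicate 2 and without either treated sensitive library, and EPHA3 had 275 and 2855 counts in the mixed libraries. Of 21 interferon genes 6 rose (12 adjusted over the list alone; camera adjusted p = 1.33e-06), and of 22 homologous recombination genes RAD51C, XRCC2, BARD1 and RAD52 rose (9 adjusted over the list alone; adjusted p = 0.00052). Both lists had an adjusted p of 0.80 with an estimated correlation. As said above, homologous recombination genes beside RAD51C lay lower on average in the treated sensitive than in the source tumours. Their rise is therefore not shown to be a trait of the mixed phenotype. The 6 interferon genes became 0 without treated sensitive replicate 1, 1 without replicate 2, 2 without mixed replicate 1 and 3 without mixed replicate 2. XRCC2, BARD1 and RAD52 lost their calls without mixed replicate 2 or either treated sensitive library, and without mixed replicate 1 the 4 homologous recombination genes became 12. The lists of replication fork protection (higher, adjusted p = 0.039, 2 of 19 risen), cholesterol and fatty acid synthesis (lower, 0.00052, IDI1 fallen) and oxidative phosphorylation (lower, 0.0043, none called) were called as well. These 3 lists had an adjusted p of 0.80 with an estimated correlation as well. The call of IDI1 was lost without either treated sensitive library, and without mixed replicate 1, 15 cholesterol and fatty acid genes and 17 of 27 oxidative phosphorylation genes fell. Adjusted over the list alone, 7 cholesterol genes were lower, and 1 oxidative phosphorylation gene was higher and 5 were lower. The 2 fork protection genes became 6 without mixed replicate 1 and 0 without mixed replicate 2 or either treated sensitive library. Of markers of other cell types, COL1A2 rose by 2.46, KRT5 of the mesothelial list fell by 1.08, and PDPN of the same list fell from 40 counts to 0, at least 13.7-fold lower against the same floor (11.1-fold at the lower 95% counting limit), calls lost without mixed replicate 2 or either treated sensitive library. In all 1124 genes differed, 680 higher and 444 lower. That count was 175 without mixed replicate 2, 131 without treated sensitive replicate 1, 96 without treated sensitive replicate 2 and 3814 without mixed replicate 1, and it was 11 with only the 4 libraries compared and 2387 with DESeq2.

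Resistant and mixed tumours differed in 71 genes, 25 higher and 46 lower. NCAM1, a neural cell adhesion molecule, rose from 5.63 ± 1.70 CPM (SD, n = 2) to 53.8 ± 17.98 CPM (SD, n = 5), and the transcription factor gene HAND1 rose from 1.92 ± 0.26 to 15.8 ± 0.94 CPM (SD, adjusted p = 0.0034 and 0.00014). The source tumours averaged 17.3 CPM of NCAM1 and 8.08 CPM of HAND1. OBP2A rose by 3.71, a call lost with only the libraries compared, and SPDEF and TFF3 fell by 2.65 and 2.37 on the log2 scale. ZNF71 fell from 81 counts in the 2 mixed libraries to 2 in the 5 resistant ones (ratio 96.7, interval 26.8 to 799). Of the 7 runs that each left out a library, ZNF71 lost its call in 6, all but the one without mixed replicate 2, SPDEF in 5 and TFF3 in 6, mixed replicate 1 among them each time. Interferon response and class I antigen presentation were called higher (camera adjusted p = 6.72e-10 and 1.28e-06, and 0.81 for both with an estimated correlation), although no member passed the test in edgeR and 3 interferon genes did in DESeq2 (1 interferon and 0 class I genes in edgeR adjusted over the list alone). Without mixed replicate 1, 2 interferon and 5 class I genes passed. All 21 interferon and all 14 class I members had log2 fold changes above 0. The count of changed genes ranged from 17 without passage 3 replicate 2 to 212 without mixed replicate 1, and it was 163 without mixed replicate 2, 39 without passage 2 replicate 2, 42 without passage 3 replicate 1 and 27 without passage 3 replicate 3.

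No gene passed the test between treated sensitive and source tumours in edgeR, where 3074 genes had an unadjusted p below 0.05 and the smallest adjusted p was 0.18. DESeq2 called 515 genes, 129 higher and 386 lower. Oxidative phosphorylation (25 of 27 members above 0, adjusted p = 2.44e-05), NF-kappaB targets (19 of 19, 0.00055) and hypoxia genes (19 of 19, 0.0056) were called higher by camera, and homologous recombination (4 of 22 above 0, 0.0012) and mitosis genes (6 of 22, 0.015) lower. None of their members passed over all genes, 8 oxidative phosphorylation genes and 1 NF-kappaB target passed as higher and 3 mitosis genes as lower adjusted over the list alone, and with an estimated correlation each had an adjusted p of 0.83.

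Passage 3 and passage 2 resistant tumours differed in 1 gene, with 610 genes at an unadjusted p below 0.05 in edgeR and 4 calls by DESeq2. IGFBP4, which binds insulin-like growth factors, was lower in the third passage (4.33 ± 0.58 CPM, SD, n = 3) than in the second (15.1 ± 1.83 CPM, SD, n = 2), with a log2 fold change of -1.81 ± 0.22 (SE, adjusted p = 0.032). Its call was lost without any single one of the 5 libraries. Camera called cholesterol and fatty acid synthesis (adjusted p = 1.11e-05) and DNA replication (0.0017) lower and NF-kappaB targets (0.0092), interferon response (0.030) and MAPK output (0.030) higher in the third passage. None of their members passed over all genes, 1 cholesterol gene passed as lower adjusted over the list alone, and with an estimated correlation the adjusted p-values were 0.84 for the lists of cholesterol, DNA replication and MAPK and 0.865 for the others. RAD51C averaged 19.3 CPM in the second and 19.9 CPM in the third passage.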

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

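All tests of explanations in this part were chosen after the result was seen, except the test of the region around RAD51C and the count of other splits of the samples. Of 65 values compared over the 5 resistant libraries, 3 had a library far from the others, about the share of 1 in 20 that chance alone gives. ZNF71 had 2 counts in passage 3 replicate 2 and none in the other 4, so the gap took the whole range (ratio 1). With the other 4 at 0 any count would give this ratio, and 2 counts lie below the floor of 3. The mean log2 CPM over the genes of DNA end protection was 5.08 in passage 2 replicate 2 and 5.03 in the other 4, a gap of 0.96 of the range. Immediate early genes averaged 3.09 in the same library and 3.798 to 3.95 in the others, a gap of 0.82 of the range. The change of IGFBP4 between resistant and source tumours differed between passages by -1.81 on the log2 scale, being 1.24 ± 0.22 (SE, adjusted p = 0.0053) in the second and -0.56 ± 0.20 (SE, adjusted p = 0.087) in the third.

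RAD51C was near 0 in the 5 sensitive libraries and present in every resistant library. A change of the whole chromosomal region is argued against, since the upper quartile of the log2 fold changes of the 23 other tested genes within 1 Mb, TEX14 left out, was 0.13. Depth is argued against as well, since resistant and source libraries differed 1.06-fold in mean total counts. Activation of the stretch around the neighbouring starts of RAD51C and TEX14, 518 bases apart on opposite strands, is a candidate explanation that the data allow, since TEX14 rose by 1.75 on the log2 scale. Whether they share a promoter was not tested, and reads near the 2 starts could not be assigned by strand. Loss of DNA methylation there would be one way to such activation, and it stays open because methylation was not measured here.

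Interferon response genes were higher in the resistant tumours. Human immune cells in these tumours are argued against, since PTPRC averaged 0.0464 CPM in the resistant libraries, although CD68, which is not specific to immune cells, averaged 14.3 CPM there and 10.5 CPM in the sensitive ones. Treatment as merely present or absent, its length left aside, is argued against. The lower quartile of the log2 fold changes of the 21 members was 1.65 between resistant and treated sensitive tumours, which were all treated. For passage number alone, as labelled, that quartile was 1.95 between passage 3 resistant and passage 3 source tumours. The labels do not say whether passages of source and of treated tumours are counted from the same start, so this value cannot decide. Passage number therefore stays open. The number of treatment rounds, treatment and passage together, and the resistant phenotype stay open as untested differences. Mouse interferon or mouse reads may contribute, as the table holds no mouse gene.

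The mixed libraries lay between sensitive and resistant ones. If each were 1 blend of cells like those of the sensitive and those of the resistant tumours, risen and fallen genes would give the same resistant-like share. In mixed replicate 2 the 53 genes that rose at least 4-fold in both comparisons gave a median share of 22.8% (quartiles 14.3 and 36.9) and the 133 that fell gave 97.0% (86.8 and 100.2), a difference of 74.2 percentage points, which argues against 1 blend there. In mixed replicate 1 the shares were 40.6% (11.8 to 62.3) and 72.1% (55.1 to 82.6), ranges that overlap. With the interferon and class I lists left out, the 43 remaining risen genes gave 37.1% (3.31 to 52.9), which does not overlap. Interferon-induced genes outside these lists, such as EPSTI1, stayed in. RAB18 alone gave 13.95% and ZNF71 alone 78.2%, so 1 blend is neither shown nor excluded in this library. In mixed replicate 2 the same 43 genes gave 26.0% (16.0 to 48.1). A candidate explanation that stays open is that loss of many of the fallen genes came before the rise of RAD51C and interferon genes in part of the cells. RAD51C alone gave 39.8% in mixed replicate 1 and 25.1% in mixed replicate 2. In mixed replicate 1 its share lay above the 13.95% of RAB18, which goes against this order for RAB18 in that library.

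Chance in the grouping of the libraries, as the source of the genes called between resistant and source tumours, was examined with other splits. Of the 56 splits of these 8 libraries into 3 and 5, 1, the real one, gave as many as its 2742 genes with the resistant tumours as 1 group, and the highest of the others gave 0. Every other split mixes source and resistant libraries in a group, which widens the spread, so few calls could arise there and the test cannot decide. With 56 splits the share cannot fall below 1 in 56.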

How the results depend on the processing

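All alternatives were fixed in advance. RAD51C kept its call in every alternative run in the 3 comparisons that called it. Of the named calls, 50 of 85 against source, 37 of 96 against treated sensitive, 3 of 35 for mixed against treated sensitive, 2 of 7 for resistant against mixed and 0 of 1 between passages did so. Over genes and comparisons, runs without a library gave 1222 results with the direction and side of the threshold kept, 390 weaker and 5 reversed, and the other alternatives 1375, 144 and 2. The cause of these changes was not tested. Leaving out a library moved the count of changed genes between 1355 and 2650 for resistant against source, 1274 and 2706 for resistant against treated sensitive, 96 and 3814 for mixed against treated sensitive, 17 and 212 for resistant against mixed, and 0 and 1 between resistant passages. It gave 0 in every run for treated sensitive against source. Passage 2 alone gave 1375 against source, 1895 against treated sensitive and 21 against mixed, and passage 3 alone 40 against mixed. DESeq2 gave 515 for treated sensitive against source, 2387 for mixed against treated sensitive, 414 for resistant against mixed and 4 between passages. Without the filter on low counts there was 1 gene for treated sensitive against source and 112 for resistant against mixed. Only the libraries compared gave 11 for mixed against treated sensitive, 9 for resistant against mixed and 0 between passages, and the resistant tumours as 1 group gave 109 against mixed. With an estimated correlation 0 gene lists were called in each of the 6 comparisons. With fry the gene list tests called 5 for resistant against source, 4 higher and 1 lower, the same numbers as camera with the preset correlation. They called 0 for treated sensitive against source, 8 for resistant against treated sensitive and 1 for mixed against treated sensitive. For resistant against mixed and for passage 3 against passage 2 resistant tumours fry called 0. The reversed values belong to PARP1 and PARP2, which passed no test. With 1 library left out, the log2 fold change of PARP1, resistant against source tumours, ranged from -0.0929 to 0.048 (highest without source replicate 3), that of PARP1, resistant against mixed, from -0.21 to 0.14 (highest without mixed replicate 2) and that of PARP1 between passages from -0.017 to 0.0996 (lowest without passage 2 replicate 1). PARP2 between passages ranged from -0.023 to 0.027, with -0.023 without passage 3 replicate 2 and -0.0041 without passage 2 replicate 1, and was -0.00069 without the filter and -0.00060 with only the libraries compared. Where a group kept 1 library, that library was assumed to vary like the other groups. Depth limits genes such as ABCB1, with 0 to 6 counts.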

Other observations

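All tests, genes and windows in this part were chosen after the values were seen. Beside RAD51C, 5 genes were below 0.5 CPM in every sensitive and at least 1 CPM in every resistant library, IL22RA1, a subunit of the interleukin-22 receptor, NCMAP, FAM26F, LINC01087 and LOC101927797. A larger set of 20 genes showed the opposite, among them ZNF71, ZNF257, ZNF676 and ZNF879 of the zinc finger family, the homeobox genes MEOX2, IRX5 and HDX, RAB18, NLRC4, EDAR and KRT4. No other of the 126 splits of these 10 libraries into 5 and 5 gave a gene of either kind. Those splits mix sensitive and resistant libraries, so a gene that separates the phenotypes could not count there. RAB18 was at 33.8 CPM in mixed replicate 1 and at 1.08 CPM in mixed replicate 2.

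Genes that changed against the source tumours were unevenly placed along the chromosomes. Over 153 windows of 20 Mb, 9 held more fallen and 18 more risen genes than the rest of the genome (Fisher's exact test, two-sided, adjusted over windows and directions). On chromosome 10, 70.9% of 79 genes from 0 to 20 Mb fell (adjusted p = 2.05e-42), against 7.42% of all tested genes. On chromosome 1 from 0 to 20 Mb, 42.5% of 207 genes rose (adjusted p = 2.53e-40), on chromosome 5 from 160 to 180 Mb 47.6% of 105 (1.97e-25) and on chromosome 7 from 140 to 160 Mb 39.1% of 110 (7.22e-18), against 7.75% of all. Genes are not independent replicates, so these p-values describe the arrangement in these libraries. The median log2 ratio to the source mean over 141 genes in the first 40 Mb of chromosome 10 was -0.70 to -0.58 in the resistant libraries, -0.13 and -0.52 in the mixed libraries and 0.07 and 0.15 in the treated sensitive ones.

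Pooled by phenotype, the mean log2 CPM over the interferon list was 6.46 ± 0.39 (SD, n = 5) in resistant and 4.18 ± 0.42 (SD, n = 5) in sensitive libraries, with an exact two-sided permutation p of 0.0079, the smallest that 5 against 5 can give, and 0.037 adjusted over 33 lists. All libraries come from the same xenograft, and the sensitive ones pool source and treated tumours. The labels do not say whether the resistant tumours share a lineage. The exact p-values in this part therefore describe these libraries and do not show a general trait of resistance. ADP-ribosylation and class I antigen presentation genes were higher with the same exact p, also without the member of largest difference. For ADP-ribosylation that member was PARP9, and PARP12, PARP14 and PARP10, also induced by interferon, stayed in. The check therefore does not show a rise of that list apart from interferon. In it 11 members lay above 0, and camera did not call it against source tumours. The mean over the stem cell list was higher by 0.42 with that p, and by 0.30 (exact p = 0.024) without LIN28A, but 7 of its 14 members were higher and 7 were not. Homologous recombination was as well, but without RAD51C the difference over the other 21 genes was 0.13 (exact p = 0.16) in place of 0.53. Cholesterol and fatty acid synthesis genes were lower with an exact p of 0.0079, also without IDI1. Ciliated cell genes were lower by 0.53 with that p, but by 0.18 (exact p = 0.10) without FOXJ1, and DNAI1 of that list rose against source tumours by 1.55, a call lost without source replicate 1, source replicate 2, either passage 2 library or passage 3 replicate 3. The lists of pancreas, liver and gut (0.64), mesothelial (-0.49) and endothelial markers (0.42) moved by as much, with exact p of 0.016, 0.016 and 0.024, or 0.058, 0.058 and 0.079 adjusted over the 33 lists. Without PRSS1, PDPN and TEK, their members of largest difference, they moved by 0.44, -0.17 and 0.26 (exact p = 0.063, 0.31 and 0.11).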
